A study of Mus musculus with 2 samples.

How the data were processed

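Droplet-based single-cell RNA sequencing was carried out on CD45+ leukocytes that had been sorted by flow cytometry from mouse tumours, with 1 library per genotype: WT and Ythdf2 KO. Per the labels' protocols, tumours from C57BL/6 mice were digested with collagenase and DNase, red cells were lysed, CD45+ cells were sorted, and libraries were made with a 10x Genomics 5′ kit and read in pairs on a NovaSeq instrument. The labels call the second sample a knockout tumour, while the design text of the series speaks of conditional knockout mice, so which cells lost Ythdf2 is not settled by the sources used here.

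The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization. The submitters' processing notes name Cell Ranger 5.0.1, Seurat 4.0.4 and the mouse build mm10, whereas Cell Ranger 6.1.1 is named per the file headers, and the conflict between these versions could not be resolved. The lowest total of a deposited barcode was 500 UMIs in either library. The matrices list 32285 genes, of which 9344 had no count in either library, and 40 symbols stand on more than 1 row. The libraries share 101 barcode sequences. With a 5′ kit, UMIs of the variable segments of antigen receptors would be plentiful. Here they made up 2.52% (WT) and 2.34% (Ythdf2 KO) of the UMIs of constant segments in T cells, counting barcodes with a second lineage, and 1.77% and 1.43% in B cells, a low yield for such a kit, so the end of the transcript that was read is left open.

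All values below were computed from these counts with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. The filters, clustering settings, marker genes, gene lists and the rule for naming genes were chosen before the data were examined. Barcodes with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept. In the WT library 466 barcodes were over 10% mitochondrial UMIs and 53 had under 200 genes, against 462 and 51 in the Ythdf2 KO library, which left 20415 and 15844 barcodes. Doublets were called with Scrublet per library, at an expected rate of 8% and 2 simulated doublets per cell. The rule was to take the 8% of barcodes with the highest scores wherever the automatic threshold marked under 0.5% or over 20%. The automatic threshold marked 0.024% of WT barcodes and 11.5% of Ythdf2 KO barcodes, so 1633 barcodes were removed by the first rule in the WT library and 1825 by the automatic threshold in the other. Over the filters tried, that threshold moved between 0.0% and 37.0%, so removal of the 8% highest scores in both libraries was added as an alternative. Exact neighbours replaced approximate ones in Scrublet so that repeated runs give identical calls.

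The 18782 WT and 14019 Ythdf2 KO cells that remained were log-normalised to 10000 UMIs and clustered together on 2000 variable genes, 30 principal components and 20 neighbours with the Leiden algorithm at resolution 1, without batch integration, since library and genotype are the same split. Mitochondrial, ribosomal protein, sex-linked and receptor variable genes were left out of the clustering. Each group of related clusters was then clustered again, and T and monocyte/macrophage cells a further time for subclasses. Groups of at least 400 cells were clustered in this way.

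Clusters were named from the fixed markers, and a class name stands for cells that resemble that type by its markers. A name needed at least 3 markers detected in at least 10% of the cells, or 4 for tissue, red cell and platelet classes. Clusters with a median depth under 1 part in 3 of their library's median and no marker of their class among their 10 leading genes stayed unnamed. This rule was applied to classes and not to subclasses, where 2 macrophage clusters meet it. Clusters with more leading markers of another class than of their own stayed unnamed as well. Barcodes in clusters that held genes of a second lineage were set aside as 2-lineage, whichever markers led them. Left out of this check were macrophage genes in cDC1, cDC2 and plasmacytoid DC clusters, and mature DC genes in cDC1 and cDC2 clusters. The limits for this, as a fraction of the level in that lineage's own clusters, were 0.07 for T and NK genes, 0.25 for macrophage genes, 0.1 for B cell and mature DC genes and 0.05 for neutrophil genes, and a subclass was left unnamed at a level of 0.07 of the other lineage. These limits, the count of detected markers and the strict form of the rule on other classes' markers were set after clusters with their cell numbers per library had been seen, over several passes. The first limit for T and NK genes was 0.05, which gave the same cell numbers per class.

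The clusters kept out of a class by these later rules held the following shares of WT and Ythdf2 KO cells. All 2-lineage barcodes together held 19.1% and 15.7%, and those that matched the markers of T cells, NK cells, neutrophils, mature DC, monocyte/macrophage cells and B cells best held 7.98% and 6.09%, 4.39% and 2.98%, 3.29% and 4.45%, 2.23% and 0.970%, 0.990% and 0.713%, and 0.256% and 0.506%. The neutrophil shares include 0.767% and 1.20% in a cluster with 3 leading T cell markers against 2 of neutrophils. A monocyte/macrophage cluster whose only leading marker was the endothelial gene Kdr held 6.06% and 3.35%. An NK cluster with the basophil gene Mcpt8 among its leading genes, behind Gzmg and other granzyme genes, held 1.08% and 0.906%. A small monocyte/macrophage cluster with the cDC1 gene Cadm1 among its leading genes, behind genes such as Slc13a3, held 0.080% and 0.342%. A shallow neutrophil cluster held 1.29% and 2.23%.

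With 1 library per group there is no test across samples, and no p-value, standard error or count of changed genes was computed from cells. Shares carry exact Clopper-Pearson intervals. Raw UMIs were summed per library and class, divided by the class total (CPM), and compared as the ratio of Ythdf2 KO over WT with the exact conditional interval for a ratio of Poisson counts. All intervals are at 95% and cover counting error only. Classes with at least 200 cells in each library were compared. The largest class, monocyte/macrophage, rested on 40925660 WT and 37123062 Ythdf2 KO UMIs, T on 3025526 and 2616510, and neutrophil, the thinnest in the WT library, on 1109093 and 1646833. In the Ythdf2 KO library mature DC were the thinnest, with 1242821 UMIs. The median log2 ratio over all genes with at least 50 UMIs in both libraries lay between -0.07 and 0.05 in every class and subclass compared.

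Genes were named by a fixed rule of size: at least 50 CPM in the higher library, at least 20% of the gene's highest class level in the same library as a guard against free RNA, and not mitochondrial, ribosomal, hemoglobin, sex-linked, receptor variable or a bare predicted name. The 10 highest and 10 lowest ratios were taken in monocyte/macrophage and in T cells, since CD8 T cells were too few, and the 3 highest and 3 lowest in NK cells, neutrophils, cDC2 and mature DC. Ythdf2 and members of the fixed lists could be named besides, without the guard of 20%. Of the 22 fixed lists, 21 were scored, and the sex-linked one served to check the samples. For each list and class, members with at least 20 UMIs over both libraries were counted as measured, and the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these libraries and is not a test. Where the text gives an interval for a median, it covers counting error only. To compare shares of cells with a UMI of a gene, cells were thinned to 1000 UMIs and shallower cells were left out.

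The comparison functions were tested on simulated data. Counts were drawn from the same Poisson model that the intervals assume, without variation between cells. Coverage near 95% therefore checks the calculation and does not show that the intervals hold for these cells. In monocyte/macrophage, the 95% interval covered the true ratio in 95.2% of 12911 unchanged genes, and in 96.0%, 94.0%, 96.0% and 94.0% of the 50 genes each that had been multiplied by 2, 0.5, 1.5 and 0.667. In T cells it did so in 96.1% of 9263 unchanged genes and in 90.0%, 96.0%, 100.0% and 98.0% of the changed ones. A list of 15 genes raised 1.5-fold reached percentile 100.0 in both classes.

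Alternatives fixed in advance were mitochondrial limits of 5% and 20%, at least 500 genes per cell, no doublet removal, Leiden resolutions of 0.5 and 2, separate clustering of each library, cells thinned to 1000 UMIs before clustering, median-of-ratios scaling, totals without mitochondrial and ribosomal genes, means of per-cell CPM, list members with at least 10 CPM, list members at 20% or more of their highest class, naming floors of 20 and 200 CPM, and cells unthinned or thinned to 2000 UMIs. Those added after the data had been seen were equal doublet removal, the earlier 2-lineage limit, clusters led by 1 or 2 markers of another class kept in their class, 2-lineage barcodes counted in the class whose markers they matched best, the same for neutrophils without the cluster led by more T cell markers, clustering without the 50 leading genes of a cluster led by Ace, shallow subclass clusters without a leading marker left unnamed, and clustering without the 530 genes that were at least 1.5 times apart between the libraries in a class and reached 50 CPM. Gene coordinates came from the GENCODE vM21 annotation of GRCm38, the assembly of mm10, in which all 374 gene identifiers looked up were found. A comparison of single genes within CD8 T cells alone was left out, since that subclass had under 200 cells in each library.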

Results

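Transcripts of single CD45+ cells, the leukocytes that a flow sort recovered from mouse tumours, were counted in 2 libraries, 1 from a WT tumour sample and 1 from a Ythdf2 KO one. Ythdf2 is a reader protein that binds m6A, the methylated adenosine of mRNA, and promotes the decay of marked transcripts. The WT library held 20886 barcodes and 168912853 UMIs, with a median of 5554 UMIs and 1851 genes per barcode. The Ythdf2 KO library held 16312 barcodes and 134066610 UMIs, with a median of 5617 UMIs and 1841 genes. Mitochondrial genes took a median of 1.33% and 1.32% of UMIs. After filtering and doublet removal, 18782 WT and 14019 Ythdf2 KO cells were analysed, with median depths of 5330.5 and 5209 UMIs. Each genotype is a single library, so no difference below has a replicate check, and the intervals given (95%) cover counting error only. Xist counts, 110886 UMIs in the WT cells and 70986 in the Ythdf2 KO cells, and at most 1 UMI of each Y-linked gene measured showed cells of female type in both.

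To check the targeted gene, Ythdf2 (ENSMUSG00000040025, a protein-coding gene on the minus strand of chromosome 4, 132184912 to 132212303 in mm10) was measured first. Over all analysed cells it reached 48.4 CPM (47.3 to 49.6) in the WT library and 46.4 CPM (45.0 to 47.7) in the Ythdf2 KO library, from 6763 and 4690 UMIs, a ratio of 0.957 (0.922 to 0.994). Its ratio was 0.975 (0.908 to 1.05) in monocyte/macrophage cells and 0.991 (0.905 to 1.09) in NK cells. In T cells it was lower in the Ythdf2 KO library at 0.686 (0.541 to 0.865), from 199 and 118 UMIs. It stood at 0.932 once T barcodes with a second lineage were counted, and at 0.944 with a mitochondrial limit of 5%. Mature DC showed 1.23 (0.970 to 1.55) and cDC2 1.15 (0.903 to 1.45, and 0.934 to 0.948 under 3 settings). Neutrophils held only 7 WT and 34 Ythdf2 KO UMIs of the gene, and their ratio of 3.27 dropped to 1.19 with 2-lineage barcodes counted (1.33 without a cluster led by more T than neutrophil markers). The sorted leukocytes held Ythdf2 transcripts at nearly equal levels in both libraries. A tag counted outside a deleted part checks nothing, and the sources used here give neither the deleted part nor the targeted cells, so this level neither backs nor contradicts the labels.

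To compare the leukocyte make-up of the tumours, the share of each cell class among all analysed cells of the CD45 sort was determined. Neutrophils, short-lived phagocytes, made up 2.65% of WT cells (2.42 to 2.89) and 6.11% of Ythdf2 KO cells (5.72 to 6.52). B cells made up 0.485% (0.390 to 0.595) and 1.76% (1.54 to 1.99), or 91 and 246 cells. Plasmacytoid DC, the main producers of type I interferon in viral infection, were also higher in the Ythdf2 KO library, at 0.463% (0.371 to 0.571) in WT and 0.892% (0.743 to 1.06). NK cells, innate killers, were lower in the Ythdf2 KO library, at 14.3% (13.8 to 14.8) in WT and 11.1% (10.6 to 11.6), as were mature DC, which carry antigen to T cells, at 2.88% (2.65 to 3.13) and 1.94% (1.72 to 2.18). These 5 directions held under every setting that gave a value, although the 91 WT B cells lost their name when each library was clustered on its own.

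Monocyte/macrophage cells were the largest class, with 44.1% of WT cells (43.4 to 44.8) and 47.4% of Ythdf2 KO cells (46.6 to 48.3). Their difference of 3.36 percentage points has no settled direction, since it lay between -3.11 and 3.36 over the settings tried and was -0.41 when the same 8% of barcodes was removed as doublets from both libraries. T cells made up 3.83% (3.56 to 4.11) and 3.90% (3.58 to 4.23), again without a settled direction (-1.82 to 1.05 points). cDC2, which present antigen to CD4 T cells, held 2.76% and 2.40% (a difference of -0.37 points that became 0.31 with separate clustering). cDC1, which cross-present antigen to CD8 T cells, held 0.479% and 0.414%, a difference of -0.07 points that ranged to 2.59 over the settings. Mast cells or basophils held 0.208% (0.148 to 0.284) and 0.093% (0.049 to 0.159), from 39 and 13 cells, with no WT cell of that name under separate clustering. Barcodes with genes of 2 lineages made up 19.1% and 15.7% and unnamed clusters 8.76% and 8.25%. The 2-lineage difference of -3.4 points has no settled direction. It became 3.05 points with a mitochondrial limit of 5%, where 15.2% of WT and 8.0% of Ythdf2 KO barcodes were removed as doublets. The shares given next rest on the main removal, of 8.0% and 11.5%. With 2-lineage barcodes counted in the class whose markers they matched best, T cells held 11.8% and 9.98%, NK cells 18.7% and 14.1%, neutrophils 5.93% and 10.6%, mature DC 5.11% and 2.91%, and B cells 0.740% and 2.26%. The neutrophil shares include a cluster of 144 WT and 168 Ythdf2 KO barcodes whose 10 leading genes hold 3 T cell markers, Foxp3 among them, against 2 of neutrophils, and without it they were 5.16% and 9.37%.

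**Figure D1:**
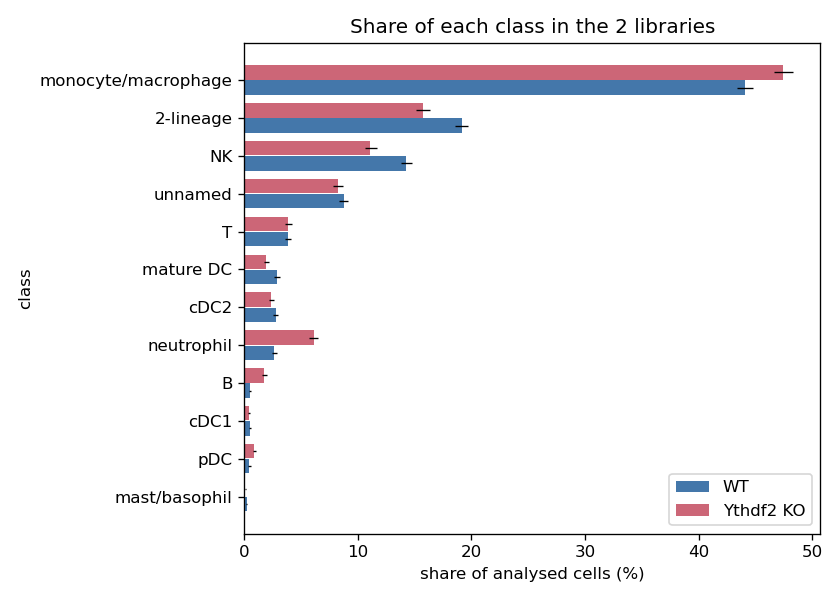
Bars give the share of each cell class among all analysed cells of the WT and Ythdf2 KO libraries, in percent, with exact 95% intervals as error bars. Neutrophils stood at 2.65% and 6.11%, NK cells at 14.3% and 11.1%, and monocyte/macrophage cells at 44.1% and 47.4%.

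**Figure D2:**
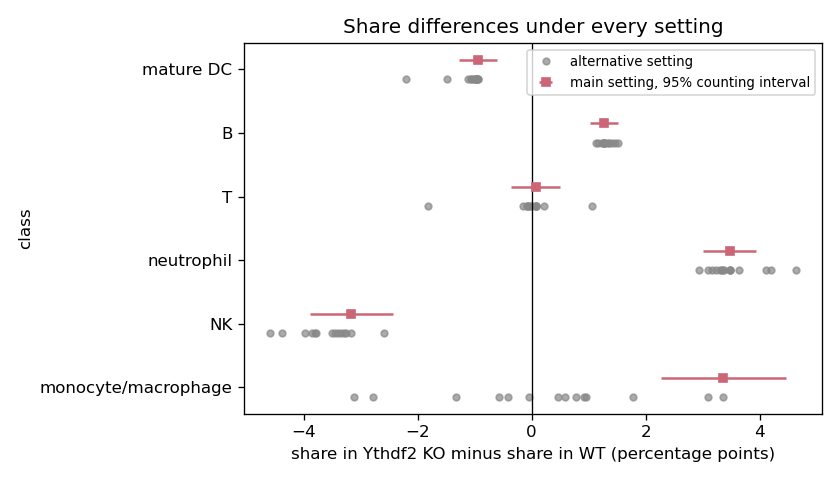
Points give the share in the Ythdf2 KO library minus that in the WT library, in percentage points, for 6 classes, with the 95% interval at the main setting and grey points for the alternative settings. The neutrophil points lie between 2.93 and 4.63 and the NK points between -4.58 and -2.59, while the monocyte/macrophage points fall on both sides of 0.

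Within the monocyte/macrophage class, cells with macrophage markers such as the complement genes C1qa and C1qb made up 42.2% of WT cells (41.1 to 43.3) and 33.2% of Ythdf2 KO cells (32.0 to 34.3). This difference of -9.02 points kept its sign under every setting that gave a value and ranged from -15.41 to -6.14. The smallest of these left out a pair of shallow macrophage clusters without a leading marker, the larger of which, led by genes such as Lars2 and Malat1, held 11% of WT and 7.17% of Ythdf2 KO cells of the class. Cells with monocyte markers such as Ly6c2 and Vcan held 37.8% and 37.6%, with no settled direction (-0.51 to 6.28 points), and clusters with neither name 20.1% and 29.3%. These shares are parts of 1 total, so a larger share without a name lowers the others, and a lower macrophage share need not mean fewer macrophages. The largest monocyte/macrophage cluster was led by Apoe in the WT library and by Ace, Adgre4 and Treml4, genes of patrolling monocytes, in the Ythdf2 KO library. Since Ace itself differed between the libraries, the size of the second is given here from clusterings without such genes. It held 8.45% of WT and 12.7% of Ythdf2 KO monocyte/macrophage cells without its 50 leading genes, and 2.19% and 9.75% without 530 genes that differed between the libraries. The macrophage difference was -12.48 points without these 530 genes.

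Among T cells, gamma-delta T cells, an innate-like type with Il17a among its leading genes here, made up 23.9% in the WT library (20.8 to 27.2) and 13.9% in the Ythdf2 KO library (11.1 to 17.1), lower under every setting that gave a value (-12.76 to -7.35 points, and -9.68 without the 530 genes). CD8 T cells, the killer subset, held 4.73% (3.30 to 6.55) and 14.5% (11.6 to 17.7) of T cells, from 34 and 79 cells, but this order is not settled. With the Cd8a-led 2-lineage clusters they held 3.91% and 3.49% of all cells, and separate clustering turned the difference from 9.74 to -8.0 points. CD4 T cells stood at 17.8% and 18.7%, regulatory T cells with Foxp3 at 8.07% and 7.69%, and T cells without a subclass at 45.5% and 45.2%. The largest T cluster of both libraries, 24.5% and 21.8% of T cells, was led by NK receptor genes such as Ncr1 and stayed unnamed.

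To compare marker genes cell by cell, monocyte/macrophage cells were thinned to 1000 UMIs, which left out 314 WT and 231 Ythdf2 KO cells. Their median depths were 4590 and 5142.5 UMIs before thinning, against 3555 and 3624 in the T cells that served as background. Cells with a UMI of Arg1, the arginine-degrading enzyme of suppressive macrophages, made up 17.0% (16.2 to 17.8) of WT and 6.68% (6.08 to 7.32) of Ythdf2 KO cells (28.9% and 12.3% unthinned, background 1.46% and 0.57%). Nos2, the inducible nitric oxide synthase, was found in 5.35% and 3.18% (12.9% and 8.56% unthinned, background 0.29% and 0.38%). The chemokine Cxcl9, which attracts T cells, was higher in the Ythdf2 KO library at 7.24% and 9.22% (12.0% and 16.0% unthinned, background 0.44% and 0.57%). Ace, the angiotensin-converting enzyme, was found in 0.95% (0.75 to 1.19) and 4.25% (3.77 to 4.77), against 3.36% and 12.6% unthinned and no T cell of 686 and 528, which allows up to 0.54% and 0.70%. The chemokine receptor Cx3cr1 stood at 3.53% and 3.82% (10.9% and 13.4% unthinned, background 0.29% and 0.19%) and the mannose receptor Mrc1 at 6.97% and 7.41% (18.2% and 19.9% unthinned, background 0.29% and 0.19%).

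In T cells thinned in the same way, with 33 and 18 cells left out and B cells of median depth 1908 and 1917 UMIs as background (0 and 3 left out), Ifng was found in 8.45% of WT (6.48 to 10.8) and 12.9% of Ythdf2 KO cells (10.1 to 16.0), against 19.2% and 28.4% unthinned and a background of 3.3% and 0.41%. The WT background, 3 of 91 B cells, allows up to 9.33%, so the WT share of Ifng is not clear of it. The granzyme Gzmb was found in 48.4% and 53.2% (69.8% and 70.9% unthinned, background 11% and 7.0%) and Tcf7, a transcription factor of naive and memory T cells, in 13.3% and 11.9% (35.2% and 31.0% unthinned, background 0% in both). Foxp3 stood at 2.92% and 2.27%, at 4.06% and 1.52% after thinning to 2000 UMIs and at 5.98% and 4.95% unthinned. No B cell of 91 and 243 held it, which allows up to 3.97% and 1.51%, so the WT share at 1000 UMIs is not clear of the background, and the size of the gap depends on the depth. For the inhibitory receptors Pdcd1, at 7.87% and 6.25% (background 0% and 0.41%), and Havcr2, at 2.77% and 2.46% (background 0% in both, with the same bounds as Foxp3), the unthinned shares of 17.3% and 20.5%, and 8.21% and 11.9%, go the other way, as do their CPM, so no order is read from them.

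Monocyte/macrophage cells of the Ythdf2 KO library held less RNA of Apoe, Saa3 and Arg1 and more of Ace and Pf4. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), a lipid carrier made by macrophages, was at 2691 CPM in the WT library and 909 CPM in the Ythdf2 KO library, a ratio of 0.338 (0.334 to 0.342). Saa3, an acute-phase protein, was at 205 and 58.4 CPM, 0.284 (0.271 to 0.298), and Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484) at 401 and 181 CPM, 0.453 (0.440 to 0.466). The lysosomal glycoprotein gene Gpnmb (95.5 and 47.8 CPM), the crosslinking enzyme Tgm2 (0.507), the protease inhibitor Timp1 (0.523), the transcription regulators Id1 (0.527) and Cebpa (0.538), the apolipoprotein Apoc2 (0.534) and the retinal reductase Dhrs3 (0.544) completed the 10 lowest ratios. Ace (ENSMUSG00000020681, chromosome 11, 105967945 to 105989964) was highest at 12.2 and 54.6 CPM, a ratio of 4.46 (4.04 to 4.93). It was followed by the collagenase Mmp13 (1.92), the chemokine Pf4 at 845 and 1476 CPM (1.75, 1.72 to 1.77), Rasgrp2 (1.69), the C-type lectin Clec4n (1.69), Ly6i (1.67), the histone gene Hist1h1e (1.65), Stap1 (1.65), Gngt2 at 248 and 404 CPM (1.63) and the integrin Itgal (1.59). Every one of these 20 ratios kept its direction and stayed within 1.5 times its value under all settings in which gene ratios were computed. None of these settings held the make-up of the class fixed. The cluster led by Ace was larger in the Ythdf2 KO library, so more cells of that kind and more RNA per cell are not told apart.

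Vegfa was lower in both subclasses, with ratios of 0.608 in macrophages and 0.647 in monocytes. Apoe (0.335, from 6033 and 2020 CPM) and Gpnmb (0.507) were lower in macrophages. Their ratios in monocytes were 0.409 (455 and 186 CPM) and 0.676, but at levels under 20% of their highest class, and Apoe was lower in T cells too (64.5 and 27.5 CPM, but a ratio of 1.98 with separate clustering), so the monocyte values are not separated from RNA of macrophages. Arg1 was at 0.192 in monocytes (117 and 22.5 CPM) and at 0.705 in macrophages, where separate clustering gave 1.07. Il1b was higher in both (1.40 and 1.54, at 6.7% and 12.6% of its level in neutrophils), and Mrc1 was higher in macrophages (1.55) with no settled order in monocytes (0.914, but 1.06 at resolution 2).

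Among the fixed lists, the hypoxia response stood out among those that macrophages themselves express. In it, 6 of 16 measured members were at least 1.5-fold lower and none was as far higher, and the median log2 ratio was -0.36 (-0.42 to -0.32), at percentile 0.0 of random lists. The growth factor Vegfa was at 215 and 125 CPM (0.581, 0.560 to 0.602), the mitophagy gene Bnip3 at 0.654 and the oxygen sensor Egln3 at 0.492. Glycolysis followed at -0.22 (-0.24 to -0.19; percentile 0.01), with 1 of 17 members 1.5-fold lower, the hexokinase Hk2 at 154 and 90.7 CPM (0.590), and the glucose transporter Slc2a1 (0.712) and the lactate dehydrogenase Ldha (0.878) nearer to even. Nuclear genes of oxidative phosphorylation went the other way at 0.21 (0.17 to 0.22; percentile 100.0), with none of 27 members beyond 1.5-fold, such as Ndufa4 at 267 and 341 CPM (1.28) and Cox5a (1.24), while the 13 mitochondrially encoded genes had a median of -0.14 (percentile 1.16). The same signs for hypoxia and oxidative phosphorylation were found in macrophages (-0.15 and 0.16) and in monocytes (-0.23 and 0.25), but both hypoxia medians are nearer to 0 than that of the whole class, and the one in macrophages stands at percentile 9.88 of random lists.

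MHC class I presentation was slightly lower in the Ythdf2 KO library, with a median of -0.15 (-0.17 to -0.13; percentile 0.27) and none of 15 members beyond 1.5-fold, including H2-K1 (0.810) and H2-Q7 (0.679), although the proteasome activator Psme2 was at 1.15. MHC class II presentation had a median of -0.02 (9 measured, none beyond 1.5-fold), with H2-Aa at 0.957 and the protease Ctss at 0.726. This class median lay between -0.06 and 0.04 over the settings. Within the subclasses it was lower, at -0.12 (-0.145 to -0.014, percentile 8.42) in macrophages and -0.09 (-0.15 to -0.05, percentile 12.93) in monocytes. The interferon gamma response stood at -0.03 (-0.06 to -0.01; percentile 25.5), with 1 of 20 members 1.5-fold higher, Cxcl9 at 178 and 217 CPM (1.22) and Cxcl10 at 1.04. Its median was -0.14 (-0.18 to -0.05, percentile 4.46) in macrophages and -0.09 (-0.13 to -0.06, percentile 5.62) in monocytes. The type I interferon response was at -0.08 (percentile 3.74), with 1 of 18 members 1.5-fold lower, Isg15 at 2230 and 1449 CPM (0.650) and Rsad2 at 0.825.

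The inflammatory macrophage list had no net direction in the whole class (-0.01, percentile 43.4). In it, 2 of 17 members were 1.5-fold higher, with the cytokine Il1b at 1207 and 2020 CPM (1.67, 1.65 to 1.69) and Ccl4 at 1.22, and Nos2 was 1.5-fold lower at 0.594. The median of this list was 0.11 (0.03 to 0.13, percentile 97.7) in macrophages and -0.05 (-0.09 to 0.02, percentile 14.85) in monocytes. The Il1b level in the Ythdf2 KO library was 12.8% of that in its neutrophils, which were more frequent there than in the WT library. T cells held only 29.4 and 54.7 CPM of it, so free RNA at that level would be a small part, while neutrophil RNA in mixed barcodes was not tested. Of the alternatively activated list, 3 of 19 members were 1.5-fold lower and none higher, with a median of -0.11 (percentile 6.67), which came to 0.01 when every cell weighed the same. Beside Apoe and Arg1 it held Trem2 (0.811), Chil3 (1.05), Spp1 (1.09) and Mrc1 (1.18). This fall was not found within the subclasses. In macrophages the median was 0.04 (-0.04 to 0.10, percentile 82.2), with 3 of 19 members higher and 2 lower. In monocytes it was -0.01 (-0.12 to 0.05, percentile 30.0), with 1 of 15 higher and 3 lower. Recruitment receptors and chemokines were at 0.09 (13 measured, 1 of them 1.5-fold lower; percentile 87.8), with the monocyte attractants Ccl2 (1.12), Ccl7 (1.22) and Ccl12 (1.23), their receptor Ccr2 (1.06), Cxcl16 (0.730) and Cx3cr1, whose ratio of 1.13 became 0.955 with separate clustering and 0.987 with a mitochondrial limit of 20%. Lipid handling and lysosome genes had a median of -0.03 (1 of 18 higher and 2 lower, with the cholesterol exporter Abca1 at 0.633), and m6A machinery -0.13 (2 of 17 lower, Ythdc2 at 0.656 and Igf2bp2 at 0.564).

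Of the remaining lists in these cells, dissociation and heat stress genes had a median of -0.11 (17 measured, none beyond 1.5-fold), DC maturation -0.02 (1 of 16 higher) and cell cycle 0.21 (3 of 20 higher), which became -0.10 when members far below their level in another class were left out. Lists of lymphocyte genes were low throughout: cytotoxic effector -0.62 (11 of 19 lower), checkpoint and exhaustion -0.50 (8 of 18), Treg function -0.55 (6 of 14), naive and memory T -0.33 (3 of 15) and early T cell activation -0.23 (3 of 15). Most of these genes belong to other classes, and with members far below another class left out the medians were near 0 for cytotoxic genes, 0.07 for checkpoint genes, 0.04 for Treg genes and 0.22 for early activation.

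T cells of the Ythdf2 KO library held more RNA of granzymes and other killing genes and less of heat shock genes, in a class of 719 and 546 cells. Serpinb9b (ENSMUSG00000021403, chromosome 13, 33027416 to 33041884), of a family that shields killer cells from their own granzymes, was at 35.7 and 130 CPM, a ratio of 3.63 (2.92 to 4.55). The granzymes Gzmf, at 432 and 1218 CPM (2.82, 2.64 to 3.01), and Gzme (2.96), the pore-forming protein Prf1 at 168 and 415 CPM (2.48, 2.23 to 2.76), the neuronal gene Nrgn (3.40), the glucose transporter Slc2a3 (1.97), Cd8b1 (1.94), Havcr2 (1.89), Rgs16 (1.80) and Serpinb6b (1.76) made up the rest of the 10 highest. Serpinb9b, Nrgn, Gzme and Gzmf also lead the CD8 cluster, the one with 34 and 79 cells. A larger share of such cells and more RNA per cell are therefore not told apart. The class also counts the unnamed cluster led by NK receptor genes, with 176 WT and 119 Ythdf2 KO cells. The lowest ratios were those of the heat shock genes Hspa1b (720 and 234 CPM, 0.325), Hspa1a (473 and 163 CPM, 0.344) and Hsph1 (0.488), then Krt83 (0.368), the ectonucleotidase Nt5e (108 and 44.0 CPM, 0.408), the suppressive cytokine Il10 (0.513), Ankhd1 (0.535), Susd6 (0.537), Znrf1 (0.539) and Dnajb9 (0.545).

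The size of these T cell ratios depended on which barcodes were counted as T cells. With 2-lineage barcodes included, Serpinb9b was at 3.40, Gzmf at 1.78, Gzme at 1.64, Nrgn at 1.38, Prf1 at 1.14, Cd8b1 at 1.18, Havcr2 at 1.26, Rgs16 at 1.12, Hspa1b at 0.502, Hspa1a at 0.601, Krt83 at 0.578 and Ankhd1 at 0.873, and with at least 500 genes per cell Prf1 was at 1.02 and Gzme at 1.35. Rgs16 was at 0.968 with a mitochondrial limit of 5%. Separate clustering of the libraries widened many of them, with Serpinb9b at 6.37, Gzme at 5.55, Gzmd at 4.90, Gzmc at 4.83, Prf1 at 3.98, Krt83 at 0.204, Nt5e at 0.239, Il10 at 0.302, Foxp3 at 0.415 and Tcf7 at 0.448. With every cell weighed the same, Serpinb9b was at 5.66, Gzme at 1.71 and Il10 at 0.926. The cytotoxic effector list kept a positive median throughout, at 0.35 (0.33 to 0.47; percentile 100.0) with 7 of 20 members 1.5-fold higher, and between 0.10 and 0.40 over the settings. Beside the genes above, Ccl3 (2.60, 1.72 with 2-lineage barcodes), Gzmd (2.29, 1.42), Ccl4 (1.56) and Gzmb (1.40) were higher. Gzma was at 1.41 and Gzmc at 1.64, but Gzma turned to 0.759 and Gzmc to 1.02 with 2-lineage barcodes, and Ifng, at 1.24, was at 2.06 with them and at 0.902 without doublet removal.

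Dissociation and heat stress genes were lower in T cells by a median of -0.66 (-0.70 to -0.58; 9 of 17 members, percentile 0.0), as was early T cell activation at -0.32 (3 of 15 lower), which shares the stress-responsive gene Egr1 (0.549) and came to 0.03 with 2-lineage barcodes. Fos, at 0.676, was at 1.04 with a mitochondrial limit of 5%. Naive and memory T genes had a median of -0.15 (3 of 15 lower), with Id3 at 0.352 (0.770 with 2-lineage barcodes), Slamf6 at 0.536 (0.838) and Tcf7 at 0.798. Checkpoint and exhaustion genes stood at 0.18 (3 of 19 higher; -0.02 with a mitochondrial limit of 5%), with Lag3 at 1.66, Pdcd1 at 1.42 and Ctla4 near even at 1.00 (0.796 to 1.21 over the settings). Treg function was at -0.16 (1 of 16 higher and 1 lower; 0.10 with 2-lineage barcodes), with Foxp3 at 0.673 (1.07). The type I interferon response was lower at -0.36 (3 of 18), with Isg15 at 0.578, and the cell cycle list higher at 0.25 (7 of 20). Of the lists of macrophage genes, recruitment was at 0.22 and lipid handling at -0.09. The other macrophage lists moved further than most of the lists above, with alternatively activated genes at -0.91 (-1.14 to -0.34; 6 of 11 lower, percentile 0.0) and inflammatory genes at 0.60 (0.24 to 0.69; 6 of 12 higher and 1 lower, percentile 100.0). Most members of these last lists stood under 20% of their highest class, and without those the medians were -0.18 and 0.03. They were -0.15 and -0.04 with 2-lineage barcodes, and 0.99 and 1.32 with separate clustering. Of the T cell genes above, Ccl3, Gzma, Gzmc, Gzmd, Isg15 and Egr1 were also under 20% of their highest class.

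RNA of inflammatory chemokines was higher in NK cells of the Ythdf2 KO library. Its levels were under 20% of the highest class, so this is not separated from RNA of other cells. Ccl3 (ratio 2.26), Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518; 2.02) and Ccl4 (1.79), which attract myeloid cells and T cells, were all higher, at 5.3%, 8.0% and 13.7% of their highest class, as were the interferon Ifng (1.47) and Pdcd1 (1.46). Together with these, the cytotoxic effector list had a median of 0.20 (0.16 to 0.23; percentile 100.0) and 3 of 20 members 1.5-fold higher, but the core killing genes were near even: Prf1 1.06, Gzma 0.997 (0.965 to 1.10 over the settings), Gzmb 0.894 and Gzmc 1.18. The largest ratios were those of the uridine phosphorylase Upp1 (2.17, 2.02 to 2.33), Serpinb9b at 177 and 343 CPM (1.93) and Ccdc184 (1.82), and the smallest those of the metallothioneins Mt2 (0.472) and Mt1 at 335 and 169 CPM (0.505) and of Tmsb15a (0.489). Recruitment receptors and chemokines were at 0.36 (4 of 12 higher), with Ccr2 at 1.57. Of barcodes typed as NK by their own UMIs and not by cluster, 16.1% of WT and 15.04% of Ythdf2 KO ones held macrophage RNA. At least 2 macrophage UMIs after thinning to 1000 UMIs were counted as such. These barcodes include ones with a second lineage, and the part of macrophage RNA in the NK class was not tested. The median of this macrophage list is therefore not separated from that RNA. Heat stress genes had a median of -0.15 (2 of 17 lower), with Hspa1a at 0.557, and mitochondrially encoded genes one of -0.19.

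Neutrophils of the Ythdf2 KO library held more RNA of interferon response genes. The type I interferon list had a median of 0.65 (0.61 to 0.72) with 12 of 17 members 1.5-fold higher and none lower, and the interferon gamma list 0.60 (0.46 to 0.70) with 9 of 17 higher and 1 lower, both at percentile 100.0. Ifit3 (2.14), Ifit2 (2.05), Rsad2 (1.62), the chemokine Cxcl10 (1.86), the GTPase Gbp2 (1.75) and the checkpoint ligand Cd274 (1.53) were higher, as were Ptgs2 (1.74), Il1b (1.38) and Cxcl2 (1.31) of the inflammatory list, whose median was 0.46 (4 of 13 higher and 1 lower). The hypoxia list, lower in monocyte/macrophage cells, stood at 0.29 here (-0.06 to 0.48; 3 of 13 higher and none lower, percentile 98.94), and at -0.20 with 2-lineage barcodes. Isg15 was at 1.13. Cxcl9 had the largest ratio at 5.78 (3.58 to 9.84), from 19 and 163 UMIs, followed by Il18 (2.93) and Ly6i (2.81). The granule genes Ngp, at 341 and 21.9 CPM (0.064, 0.044 to 0.090), and Ltf (0.114) and the secreted factor Prok2 (0.114) had the smallest. Most Ythdf2 KO neutrophils lay in clusters led by Cxcr2 (166 and 436 cells) and G0s2 (168 and 339), while WT neutrophils were spread evenly over these and a cluster led by Retnlg and Ngp (163 and 82). A different mix of such cells and a change in RNA per cell are therefore not told apart, for the interferon lists and for Ngp and Ltf alike. With 2-lineage barcodes, save the cluster led by more T than neutrophil markers, Cxcl9 was at 1.59, Il18 at 1.18, Ly6i at 1.66, Ifit2 at 1.34, Isg15 at 0.899, Ltf at 0.267 and Ngp at 0.097. With that cluster as well, Cxcl9 was at 1.39, Isg15 at 0.843 and Ltf at 0.326, and with every cell weighed the same Cxcl9 was at 2.93, Ltf at 0.410, Prok2 at 0.204 and Ngp at 0.109. The medians of the interferon lists were lower with 2-lineage barcodes but still above 0, at 0.26 for type I and 0.14 for interferon gamma without that cluster and 0.23 and 0.11 with it. MHC class I genes were at 0.25, but at -0.12 and -0.08 with these barcodes. In the same cells mitochondrially encoded genes were at 0.47, heat stress genes at 0.34 (0.07 with 2-lineage barcodes save that cluster, and -0.05 with it) and cytotoxic genes, which belong to T and NK cells, at -0.62 (1 of 17 higher and 10 lower). The cytotoxic median turned to 0.52 with members under 20% of their highest class left out.

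Mature DC of the Ythdf2 KO library held more Il12b (ENSMUSG00000004296, chromosome 11, 44400063 to 44414033), the subunit of interleukin 12 that drives T cell and NK responses, at 510 and 1183 CPM, a ratio of 2.32 (2.15 to 2.50). The DC maturation list had a median of 0.17 (0.09 to 0.22) with 2 of 17 members 1.5-fold higher, Il12b and the chemokine Ccl22 (1.52). Tnfsf4 (1.46), Fscn1 (1.19) and Ccr7 (1.13) were nearer to even. Interferon genes were lower in the same cells: the type I list had a median of -0.41 (6 of 18 lower) and the interferon gamma list one of -0.33 (8 of 19 lower), with Isg15 at 0.634, Cxcl10 at 0.550 (0.992 with 2-lineage barcodes) and Ifit3 at 0.534 (0.940), of which the last 2 were under 20% of their highest class. With 2-lineage barcodes both list medians came close to 0, at -0.06 and -0.07. Cytotoxic genes, which belong to T and NK cells, were lower alike at -0.34 (5 of 16 lower). Glycolysis was at -0.31 (1 of 16 lower; Ldha 0.723, Gapdh 0.833) and heat stress at -0.19 (4 of 17 lower), with Hspa1a (0.458) and Hspa1b (0.486) among the smallest ratios beside Sct (52.9 and 18.5 CPM, from 135 and 23 UMIs). Igfbp4 (2.80), Mfge8 (2.58), an adhesion protein of exosomes, and Serpinb1a (2.45, but 1.34 with 2-lineage barcodes and 1.44 with a mitochondrial limit of 20%) had the largest.

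cDC2 shared part of the monocyte/macrophage differences. Clusters of this class were not checked for macrophage genes, so the values below are not separated from macrophage cells or RNA in it. Vegfa (0.513) and Bnip3 (0.684) were lower and the hypoxia list had a median of -0.32 (-0.46 to -0.12; 2 of 14 lower), oxidative phosphorylation genes were at 0.11 (none of 27 beyond 1.5-fold), Il1b was at 1.70 (16.6% of its level in neutrophils) and H2-K1 at 0.878, with MHC class I genes at -0.12. Mmp13 (4.10, from 45 and 130 UMIs), Mmp12 (3.05) and Pf4 at 169 and 501 CPM (2.97) had the largest ratios and Apoe (0.299), the receptor kinase Axl (0.437) and Id1 (0.478) the smallest. The size of the first depended on the clustering, with Mmp13 at 1.45 and Mmp12 at 6.36 at resolution 0.5, and with separate clustering of the libraries Mmp13 was at 46.7, Pf4 at 17.7 and Apoe turned to 1.93 (0.548 with a mitochondrial limit of 20%).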

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

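The tests in this part were chosen after the results that they bear on had been seen.

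A cluster led by Rhox5, a homeobox gene of germ and tumour cells, made up 0.25% of the WT cells (47 cells) and 1.41% of the Ythdf2 KO cells (198 cells, 1.22 to 1.62). It was set apart because it lies outside every leukocyte class compared above and holds signal all the same. Rhox5 reached 738 and 946 CPM there against 3.42 and 5.37 CPM in all other cells, the collagen gene Col3a1 406 and 397 against 0.83 and 1.10, and the surface protein gene Tm4sf1 203 and 265 against 0.85 and 1.31. Ythdf2 stood at 47.5 and 51.4 CPM in the cluster, a ratio of 1.08 (0.667 to 1.87, from 18 and 183 UMIs). This value has the same limit as the level over all cells, since the deleted part is not given. Ptprc, which encodes the sorted antigen CD45, stood at 200 and 70.3 CPM against 864 and 855, or 23.2% and 8.20% of the level in the other cells. Tumour or stromal cells carried through the sort are a candidate source, but the WT value of 23.2% lies above the limit of 20% set for that reading, and since the WT cluster also held the macrophage gene C1qa at 390 CPM (69.2 in the Ythdf2 KO cluster, 674 and 692 in other cells), which would bring Ptprc with it, this stays open, as does a biological difference between the tumours.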

How the results depend on the processing

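No paired analysis was possible because the labels give 1 library per group. The settings that count 2-lineage barcodes in their class, with or without a cluster led by more markers of another class, that fix the doublet share at 8%, that keep clusters led by markers of another class, that leave shallow subclass clusters unnamed, that set the 2-lineage limit for T and NK genes at 0.05, and that leave genes of the Ace cluster or genes differing between the libraries out of the clustering were chosen after seeing the data.

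Over 15 settings, the share difference kept its sign for neutrophils (2.93 to 4.63 points), and over 14 each for plasmacytoid DC (0.27 to 0.5), NK cells (-4.58 to -2.59), mature DC (-2.2 to -0.94), gamma-delta T cells among T cells (-12.76 to -7.35) and macrophages (-15.41 to -6.14), and over 13 settings for B cells (1.13 to 1.52). In monocyte/macrophage cells the hypoxia median stayed between -0.36 and -0.32 and that of nuclear oxidative phosphorylation genes between 0.19 and 0.24 over 16 settings, and the Apoe ratio between 0.334 and 0.351 over 14. Some of the settings counted here only repeat the main result. The 2-lineage limit of 0.05 gave the same cell numbers per class. Keeping clusters led by markers of another class did so for neutrophils, T cells, B cells and mature DC. No T cluster was shallow enough for the setting on shallow subclass clusters to bear on gamma-delta T cells. Gene ratios and list medians were not computed on thinned cells or on clusterings without chosen genes, and subclass shares were not computed with 2-lineage barcodes counted. No cluster took the name of CD4 T cells, cDC1 or cDC2 on thinned cells, of regulatory T cells or mast cells and basophils at resolution 0.5, or of mast cells and basophils without doublet removal, so these gave no value there. With each library clustered on its own, no WT cluster took the name of B cells or of mast cells and basophils, so there is no difference for them, and 5 lists in a class had too few members left under the limit of 20%. For the values that turned or moved, given next, the cause was not tested.

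With members under 20% of their highest class left out, list medians were MHC class II 0.04, inflammatory -0.09, early T cell activation 0.22, Treg 0.04, cell cycle -0.1 and checkpoint 0.07 in monocyte/macrophage cells, cytotoxic 0.31 in T cells, cytotoxic 0.52 in neutrophils, lipid handling -0.02 in NK cells. With a mitochondrial limit of 20%, the share differences in points were NK -3.97, macrophage -12.51 and monocyte/macrophage 0.46, list medians were MHC class II -0.06 in monocyte/macrophage cells, MHC class II 0.3 in NK cells, and gene ratios were Cx3cr1 0.987 in monocyte/macrophage cells. Without doublet removal, the share differences in points were macrophage -11.77, monocyte/macrophage -0.04 and Ace cluster 8.29, list medians were MHC class II -0.04 and interferon gamma -0.09 in monocyte/macrophage cells, MHC class II 0.4 in NK cells, and gene ratios were Ifng 0.902 in T cells. At Leiden resolution 0.5, the share differences in points were macrophage -11.46, monocyte/macrophage 0.59 and Ace cluster 8.8, list medians were MHC class II -0.04 and interferon gamma -0.09 in monocyte/macrophage cells, cytotoxic 0.3 in T cells, and gene ratios were Ifng 0.908 in T cells. At Leiden resolution 2, the share differences in points were macrophage -12.13, monocyte/macrophage 1.77 and neutrophil 4.11, list medians were MHC class II -0.06 and interferon gamma -0.07 in monocyte/macrophage cells, cytotoxic 0.14 and MHC class II 0.22 in NK cells, cytotoxic 0.3 and glycolysis -0.01 in T cells, and gene ratios were Ythdf2 0.878 and Gzma 0.932 in T cells. With each library clustered on its own, the share differences in points were CD8 T -8.0, T 1.05, macrophage -15.23, monocyte/macrophage -3.11, Ace cluster 4.79 and cDC2 0.31, list medians were MHC class II 0.02 and interferon gamma -0.08 in monocyte/macrophage cells, cytotoxic 0.12 in NK cells, DC maturation 0.18 in cDC2, alternative activation 0.99 in T cells, naive -0.02 in mature DC, and gene ratios were Apoe 1.984 in T cells, Apoe 1.925 in cDC2, Arg1 1.07 and Bnip3 1.192 in macrophages, Cx3cr1 0.955 in monocyte/macrophage cells. With clusters led by 1 or 2 markers of another class kept, the share differences in points were monocyte/macrophage 0.91 and Ace cluster 8.35, while list medians were MHC class II -0.04 and interferon gamma -0.09 in monocyte/macrophage cells. With a mitochondrial limit of 5%, the share differences in points were NK -4.38, macrophage -13.32, mature DC -1.48, monocyte/macrophage -2.78, neutrophil 2.93, Ace cluster 7.99 and 2-lineage 3.05, list medians were cytotoxic 0.17, checkpoint -0.02 and glycolysis -0.03 in T cells, interferon gamma -0.09 in monocyte/macrophage cells, DC maturation 0.07 and early T cell activation 0.04 in cDC2, MHC class II 0.1 in NK cells, MHC class II 0.01 in neutrophils, and gene ratios were Ythdf2 0.944, Fos 1.037, Gzma 0.746 and Rgs16 0.968 in T cells. With at least 500 genes per cell, the share differences in points were macrophage -15.41, monocyte/macrophage -0.58 and Ace cluster 10.34, list medians were cytotoxic 0.1, glycolysis -0.13 and mitochondrially encoded 0.02 in T cells, interferon gamma -0.07 in monocyte/macrophage cells, and gene ratios were Ythdf2 0.971, Fos 1.01, Gzma 0.57 and Gzmc 0.983 in T cells. With 2-lineage barcodes counted, the share differences in points were NK -4.58, T -1.82, mature DC -2.2 and neutrophil 4.63, list medians were cytotoxic 0.17, early T cell activation 0.03, Treg 0.1, glycolysis -0.11 and inflammatory -0.04 in T cells, MHC class I -0.08 and heat stress -0.05 in neutrophils, MHC class II 0.12 in mature DC, lipid handling -0.13 in NK cells, and gene ratios were Ythdf2 0.932, Foxp3 1.07 and Gzma 0.759 in T cells, Ythdf2 1.193 and Isg15 0.843 in neutrophils. With the 8% highest doublet scores removed in both libraries, the share differences in points were macrophage -13.54, monocyte/macrophage -0.41 and Ace cluster 8.52, while list medians were interferon gamma -0.08 in monocyte/macrophage cells, MHC class II 0.24 in NK cells. With 2-lineage barcodes counted, save the cluster led by more T cell markers, the share differences in points were neutrophil 4.2, list medians were DC maturation -0.09 and MHC class I -0.12 in neutrophils, and gene ratios were Ythdf2 1.326 and Isg15 0.899 in neutrophils. Clustered without the genes that differed between the libraries, the share differences in points were macrophage -12.48, monocyte/macrophage 0.78 and Ace cluster 7.56. With shallow subclass clusters without a leading marker left unnamed, the share differences in points were macrophage -6.14. With every cell thinned to 1000 UMIs, the share differences in points were monocyte/macrophage 0.95 and Ace cluster 9.16. Clustered without the 50 leading genes of the Ace cluster, the share differences in points were monocyte/macrophage -1.32 and Ace cluster 4.22. With only members of at least 10 CPM, list medians were Treg 0.04 and checkpoint 0.07 in monocyte/macrophage cells. With every cell weighed the same, list medians were interferon gamma 0.01 in T cells, lipid handling -0.01 in NK cells.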

Other observations

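In the gene lists not described above, NK cells of the Ythdf2 KO library had a median log2 ratio of 0.12 for MHC class I genes (0.07 to 0.15, none of 15 beyond 1.5-fold) and of -0.18 for the hypoxia response (-0.23 to -0.04, none of 15; mature DC stood at -0.17, T cells at 0.01 and neutrophils at 0.29), and glycolysis stood at -0.13 (1 of 17 higher). In macrophages alone, MHC class I genes were at -0.31 (-0.35 to -0.20) and recruitment genes at 0.18 (0.12 to 0.24). Variable segments of the T cell receptor made up 2.52% and 2.34% of the UMIs of its constant segments in T barcodes.

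The tests in the rest of this part were chosen after the results had been seen. Clusters part barcodes by the macrophage RNA they hold, so barcodes were typed by their own UMIs here: at least 2 of Cd8a and Cd8b1 and 2 of the Cd3 genes for CD8 T cells, and at least 2 of Ncr1, Klrb1c and Klre1 for NK cells, with the larger of the Cd3 and NK sums deciding. Of the CD8 T barcodes, 51.8% of WT and 42.1% of Ythdf2 KO ones held at least 2 macrophage UMIs after thinning to 1000 UMIs, against 16.1% and 15.04% of NK barcodes. Random pairs formed at loading would touch both alike, but the lowest ratio of these shares was 1.89 over both libraries, with and without doublet removal and with 1, 2 or 3 UMIs needed for the type. This does not settle the part of such doublets. The barcodes were not matched on depth here, with medians of 17809 UMIs for CD8 T and 12275.5 for NK in the Ythdf2 KO library without doublet removal. CD8 T barcodes also needed UMIs of 2 gene sets, and thinning leaves fewer macrophage UMIs beside a partner rich in RNA. Free RNA in the droplets would also reach both alike at the same depth, but the lowest ratio was 1.72 over the bands of 5000 to 15000 and from 15000 UMIs, with and without doublet removal. Among barcodes of 1000 to 5000 UMIs the shares, 11.6% and 6.45% of only 43 and 31 CD8 T barcodes against 5.52% and 5.67%, had overlapping intervals, so nothing is excluded there. The source of the macrophage RNA in NK barcodes was not tested. T cells attached to macrophages, or T cells holding macrophage RNA they took up, may account for part of the macrophage RNA in CD8 T barcodes, which was not tested here.

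The Ace cluster, B cells and neutrophils were all higher in the Ythdf2 KO library, and all 3 are found in blood. More blood in that sample would also raise naive T cells, led here by Lef1 and Ccr7, and their share ratio was 1.13 (0.75 to 1.69, from 57 and 48 cells) against 3.62 (2.84 to 4.66) for B cells and 2.31 (2.07 to 2.59) for neutrophils. With so few naive T cells this leaves the question open, and no blood sample was measured. For the Ace cluster, leaving its 50 leading genes out of the clustering lowered the difference from 11.26 to 4.22 points, and leaving out 530 genes that differ between the libraries lowered it to 7.56. Without its 50 leading genes the cluster itself was also drawn otherwise, with 701 WT cells in place of 213. It held 731 WT cells with a mitochondrial limit of 20% and 806 at Leiden resolution 0.5, where no gene was left out. How far its genes draw the difference is therefore left open, as is a biological difference between the tumours.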
